A study of Mus musculus with 8 samples.

How the data were processed

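RNA levels were measured on Affymetrix whole-transcript arrays in 8 mouse samples. Per the labels, they comprise purified cerebellar granule neuron precursors (GNPs) of 2 genotypes taken at postnatal day 8 and medulloblastomas of adult mice. Per the labels' protocols, GNPs came from dissected cerebella, either of mice in which Math1-Cre switches on a FLAG-tagged Gli1 at the Rosa locus or of Ptc+/- mice, which carry 1 targeted Ptch1 allele. Tumours came from mice with both alterations. Total RNA was extracted with Trizol, ribosomal RNA was reduced, and cDNA was amplified, fragmented and labelled with biotin, per the labels' protocols. Age, preparation and the joint presence of both alterations therefore differ between tumours and GNPs along with the disease. No comparison of the 2 kinds of sample can separate them.

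The deposited values are an intensity per transcript cluster on a linear scale, given as whole numbers for 16317 rows on each array. The submitters' processing notes name the genome build mm8. The background correction, the summary over probes and any scaling are not given in the sources used here. Median intensities per array ran from 109 to 310, a ratio of 2.84, so the deposited intensities are not normalized between arrays. The design written before the data were examined assumed that normalized values would be tested as deposited. Because they were not normalized, the linear intensities were quantile normalized over all 8 arrays, values under 0 were set to 0, and log2(intensity + 1) was tested. A fold change is thus on the log2(intensity + 1) scale, which understates changes of dim transcripts. No detection p-value accompanies the intensities used here, so a dim row cannot be told from background, and the number of arrays limits the precision.

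Transcript clusters were named through the platform annotation. Of the 16317 rows, 14551 had 1 gene symbol, 1146 had several, and 620 were unnamed here. There were 14351 distinct symbols, 197 of them on more than 1 row. Entrez identifiers of 14517 rows were found in a gene table of assembly GRCm38, and 0 symbols changed on update. Because the builds differ, no genome positions are given. A gene is represented by its row with the highest mean over the 8 arrays. Where the rows of a named gene disagree, both values are given.

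Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 3 group means was fitted to all 8 arrays with lmFit, followed by eBayes, which estimated 2.45 prior degrees of freedom beside 5 residual ones. P-values were two-sided and Benjamini-Hochberg adjusted over all rows, with a threshold of 0.05. The 3 comparisons were medulloblastoma against Ptc+/- GNPs, Gli1-FLAG GNPs against Ptc+/- GNPs, and medulloblastoma against Gli1-FLAG GNPs. The third equals the first minus the second, so the comparisons are not independent. The labels call the replicates biological. Nothing in the sources used here says that each came from a separate animal, so the p-values measure only the spread between these samples, which may be technical in part.

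Before the data were examined, 35 gene lists were fixed for pathways and cell types of the cerebellum, as were the tests, most of the alternatives and the rule for named genes. The 34 lists other than the sex-linked check were tested with camera at a preset correlation of 0.01 over 14351 genes. The adjustment was over the lists with at least 3 measured members. Camera was repeated with a correlation estimated per list, and fry was run beside it. The p-value of fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Members past the threshold were counted after adjustment over all rows and also adjusted over the list alone.

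Genes were named by rule. The rule took the measured hedgehog targets in every comparison and, for tumours against Ptc+/- GNPs, the 10 largest rises and 10 largest falls among rows past the threshold whose arrays did not overlap. It took the 5 lowest p-values in each direction for the GNP groups, since fewer than 5 genes passed there, and 5 rises and 5 falls for tumours against Gli1-FLAG GNPs. It also took the up to 4 members of each list with the lowest p. Unnamed clones and gene models were passed over. Y-linked genes served as a check of the labels.

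Signal was described by the percentile rank of a gene within each array, which depends on its probes and does not establish presence or measure abundance between genes. A gene counted as high in a group if it ranked above the 50th percentile on every array of it. Alternatives covered the arrays in the fit, the replicate number as a block, 2 other normalizations, a filter on dim rows, eBayes with trend and robust settings, array weights per group, a 2-fold minimum, 1 row per symbol, an offset of 16, and each array left out in turn. With the replicate number as a block, medulloblastomas 3 and 4 drop out of every comparison, since no other sample has their number. A setting without the arrays richest in other cell types was added after seeing the data. The ChIP-chip data that the series design mentions were not used here.

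The steps were tested on simulated data with the spread seen in each group, 16317 genes and 100 changed genes per fold size. For tumours against Ptc+/- GNPs, limma recovered 20% of the 2-fold and 83% of the 4-fold changes with 2 false calls. For the GNP groups it recovered 2% and 66% with 0 false calls, and for tumours against Gli1-FLAG GNPs 19% and 80% with 0 false calls. With equal spread in the groups it recovered 22% and 86%, 4% and 67%, and 27% and 84% in the same order, with 7, 7 and 8 false calls (6.1%, 9% and 6.7% of calls), shares above the nominal level. Camera, run on data with equal spread, called 20 of 20 simulated lists shifted by 2-fold and 0 of the others among 200. All simulated genes varied independently, so this cannot show how often camera falsely calls lists whose genes move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with pandas 2.3.3 and numpy 2.4.6 for the tables.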

Results

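Transcript levels were measured on 8 arrays, 1 per sample, in 3 groups. There were 2 samples of GNPs that express a FLAG-tagged Gli1, 2 samples of GNPs from Ptc+/- mice, and 4 medulloblastomas from mice with both alterations. GNPs are the dividing precursors of cerebellar granule neurons, driven by Sonic hedgehog, and are the cells from which hedgehog-type medulloblastoma arises. Ptch1 encodes the hedgehog receptor that restrains the pathway, and Gli1 encodes a transcription factor that the pathway both induces and uses. Median intensity per array was 116 and 109 in the Gli1-FLAG GNPs, 283 and 125 in the Ptc+/- GNPs, and 170, 186, 134 and 310.0 in the tumours. After normalization the median SD between replicates was 0.0899 log2 units in Gli1-FLAG GNPs, 0.140 in Ptc+/- GNPs and 0.299 in tumours. The mean correlation between replicates across rows was 0.987, 0.979 and 0.953, with rows not being independent replicates.

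Tumours lay apart from GNPs on the first principal component, which held 45.3% of the variance (35.74 to 49.38 against -47.77 to -37.31). The following components, with 17.9% and 14.6%, parted the tumours from each other, with medulloblastoma 2 at 46.13 and medulloblastoma 4 at -58.51 on the second component. Medulloblastoma 3 stood apart at -58.25 on the next. As a check of the samples, the Y-linked Eif2s3y had log2 intensities of 4.54 and 4.12 on the Gli1-FLAG GNP arrays, 8.99 and 9.01 on the Ptc+/- GNP arrays, and 8.97, 8.32, 4.55 and 8.84 on the tumour arrays. Kdm5d, also Y-linked, was at 4.28 and 4.25, at 8.07 and 7.91, and at 8.01, 7.39, 4.55 and 7.80. Genotype and the Y-linked signal therefore went together in the GNP groups. The sex of the animals is not in the labels used here.

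The engineered genes were read on every array first. Gli1 (transcript cluster 6777932) had log2 intensities of 9.24 and 9.38 in Ptc+/- GNPs, 10.08 and 10.19 in Gli1-FLAG GNPs, and 10.58, 10.42, 10.52 and 10.90 in the tumours. It was higher in each Gli1-FLAG sample than in both Ptc+/- GNP samples. Whether its probes detect the tagged transcript is not known here. Ptch1 (transcript cluster 6813844) was at 9.98 and 9.99, at 10.05 and 10.12, and at 9.78, 9.85, 10.50 and 10.38. This value summarises the whole transcript cluster, with probe positions unknown here, so it does not check the targeted allele.

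The series set out to find which genes are expressed in each kind of sample. Of 16317 rows, 6696 ranked above the 50th percentile on every array of all 3 groups, 289 did so only in tumours, and 970 did so in both GNP groups but not in tumours. In all, 7872 rows were high in Ptc+/- GNPs, 7993 in Gli1-FLAG GNPs and 7175 in tumours. The rule asks more of the tumours, with 4 arrays that vary more, than of each GNP group with 2. Lower counts in tumours, here and in the lists below, can therefore come from the rule and do not show a loss of expression. Of the 11 measured hedgehog targets, 7 were high in Ptc+/- GNPs, 8 in Gli1-FLAG GNPs and 8 in tumours. Ranks compare rows whose probes differ, so they describe signal on the array and do not measure the level of one transcript against another. The D-type cyclin gene Ccnd2 was among the brightest rows in every group (percentile 99.7 ± 0.02, SD, n = 2, in Ptc+/- GNPs and 99.8 ± 0.04, SD, n = 4, in tumours), as was the cerebellar transcription factor gene Zic1 (99.1 ± 0.29 and 99.2 ± 0.39). Gli1 ranked at the 81.1 ± 1.76 percentile (SD, n = 2) in Ptc+/- GNPs, 92.4 ± 0.74 (SD, n = 2) in Gli1-FLAG GNPs and 95.8 ± 1.14 (SD, n = 4) in tumours. Of 15 measured pathway components, 12 were high in each GNP group and 9 in tumours. Those that dropped out of the high class in tumours were Gli3 (percentile 57.2 in Ptc+/- GNPs and 19.4 in tumours), Stk36 (64.5 and 47.3) and Ift88 (54.8 and 43.5). Of 19 GNP identity genes, 17 were high in each GNP group and 16 in tumours, with Tfap2b falling out (60.5 and 20.5).

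The differential comparison named in the design set the tumours against Ptc+/- GNPs, to find which transcripts distinguish the tumours from precursors that carry the same Ptch1 alteration. Gli1 rose 2.45-fold in the tumours (log2 10.60 ± 0.21, SD, n = 4, against 9.31 ± 0.10, SD, n = 2), and Atoh1, the transcription factor that defines GNPs, rose 4.26-fold (11.51 ± 0.49 against 9.42 ± 0.01). Gli3, which encodes the main repressor form of the Gli family, fell from 7.98 ± 0.12 to 4.79 ± 0.63. Of the immediate early genes 14 of 21 fell, Fos among them, as did 9 of 16 markers of blood vessel endothelium, and the complement genes C1qa, C1qb and C1qc of microglia rose. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.266, 0.897 and 0.959). The cell cycle inhibitor genes Cdkn2a and Cdkn2b and the G1 kinase gene Cdk6 rose. In limma's fit 2687 of 16317 rows (16.5%) passed the threshold, 1231 rising and 1456 falling, and 1252 of them changed at least 2-fold (579 up, 673 down). All tumour arrays lay above or below both Ptc+/- GNP arrays in 42% of rows, where chance gives 13.3%. Rows share arrays and are not independent, so this excess was not tested. With each array centred on its median the split was 1713 rises and 1352 falls, since that scaling moved the median of all rows from 0.01 to 0.13, and 2168 calls were shared. With 2 control arrays the count leaned on each of them. It was 128 without Ptc+/- GNP replicate 1 and 460 without replicate 2, the lone array then being assumed to vary like the other groups. Without Gli1-FLAG GNP replicate 1 or 2, whose group is not in this comparison but enters the normalization and the shared spread, it was 1231 or 1227, without medulloblastoma 1 it was 1751, and it was 40 without both Ptc+/- GNP 1 and medulloblastoma 2, a setting chosen after seeing the data. Of 104 calls of named genes, 20 held on leaving out each array in turn, and 0 changed direction. Of the 104, 20 held without Ptc+/- GNP replicate 1, 39 without replicate 2, 76 without each Gli1-FLAG array and 83 without medulloblastoma 1. With the replicate number as a block, which drops medulloblastomas 3 and 4, 86 held. With arrays centred on their medians 95 held, and with only the arrays of these groups 77.

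Of 11 measured hedgehog targets, 4 rose and 0 fell (4 and 0 adjusted over the list alone). Beside Gli1 (log2 fold change 1.29 ± 0.17, SE; adjusted p = 0.00666), these were the cyclin gene Ccnd1 (1.12 ± 0.20; adjusted p = 0.0148), the proto-oncogene Mycn (0.79 ± 0.16; adjusted p = 0.0183) and the secreted Wnt modulator Sfrp1 (0.85 ± 0.23; adjusted p = 0.0450). Each was higher in 4 of 4 tumours than in both Ptc+/- GNP samples. Tumours carry the tagged Gli1 and Ptc+/- GNPs do not, so the rise of Gli1 follows that difference too. Against Gli1-FLAG GNPs Gli1 did not pass. Ptch1 itself differed by 0.15 ± 0.24 (adjusted p = 0.710), Hhip, which encodes a hedgehog-binding inhibitor, by 0.09 ± 0.56, Ccnd2 by 0.19 ± 0.13 (adjusted p = 0.347), and the Polycomb gene Bmi1 by 0.28 ± 0.15. Igf2 differed by -0.20 ± 0.76, with Ptc+/- GNP arrays at 10.06 and 7.06. Bcl2 (-0.19 ± 0.18) and Nkx2-2 (-0.03 ± 0.34, and 0.29 with arrays centred on their medians) did not pass either. The list of hedgehog targets had a median of 0.19 (0.29 with 3 rises with arrays centred on their medians) and missed camera's threshold (adjusted p = 0.0552; adjusted p = 0.594 with an estimated correlation, fry adjusted p = 0.0300), but passed without Ptc+/- GNP replicate 1 (adjusted p = 0.0242) or medulloblastoma 2 (adjusted p = 0.0372). Gli1 lost its call without Ptc+/- GNP replicate 1 (adjusted p = 0.0815). Ccnd1 and Mycn lost theirs without replicate 1 (adjusted p = 0.122 and 0.151) or replicate 2 (0.0804 and 0.0743). Sfrp1 lost its call on leaving out either Ptc+/- GNP array (0.210 and 0.176), either Gli1-FLAG array (0.0853 and 0.0855), medulloblastoma 1 (0.0927) or medulloblastoma 2 (0.0662), and with arrays centred on their medians (0.0646).

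Among 15 measured hedgehog pathway components, 2 rose and 4 fell (2 and 4 adjusted over the list alone). Gli3 fell by 3.19 (SE 0.37; adjusted p = 0.00445), to near the bottom of the scale on medulloblastomas 3 and 4 (4.25 and 4.29). The kinase gene Stk36 fell by 1.15 (adjusted p = 0.0126) and Ift88, which encodes a part of the transport machinery of the primary cilium, by 0.88 (adjusted p = 0.0134). Boc, which encodes a hedgehog co-receptor, rose by 1.02 (adjusted p = 0.0176). The list had a median of 0.09 but a mean of -0.17, and camera's direction was down (adjusted p = 0.636). Without Ptc+/- GNP replicate 1 all 4 named calls were lost, with adjusted p = 0.0556 for Gli3 and 0.122 for Boc as the extremes, and without replicate 2 Boc, Ift88 and Stk36 lost theirs (0.0977, 0.0889 and 0.0687).

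Of 19 measured genes of GNP identity, 2 rose and 6 fell (3 and 7 adjusted over the list alone). Atoh1 rose by 2.09 (SE 0.30; adjusted p = 0.00800) on its brighter row and by 2.23 on its other row. The homeobox gene Barhl1 rose by 0.94 (adjusted p = 0.0214). Mfap4 fell by 1.99 (adjusted p = 0.0276), the homeobox gene Meis1 by 0.59 (adjusted p = 0.0277), and Tfap2b by 3.38 (adjusted p = 0.0402). The list as a whole did not shift (median -0.05; adjusted p = 0.369). All 5 of these calls were lost without either Ptc+/- GNP array and, except for Atoh1, without either Gli1-FLAG array, with the highest adjusted p at 0.191 for Tfap2b without Ptc+/- GNP replicate 1. Meis1 and Tfap2b also lost theirs without medulloblastoma 1 (0.0582 and 0.0651), and Tfap2b without medulloblastoma 3 (0.0582) or 4 (0.0574), and Meis1 with the replicate block (0.0599) or with arrays centred on their medians (0.123).

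**Figure D1:**
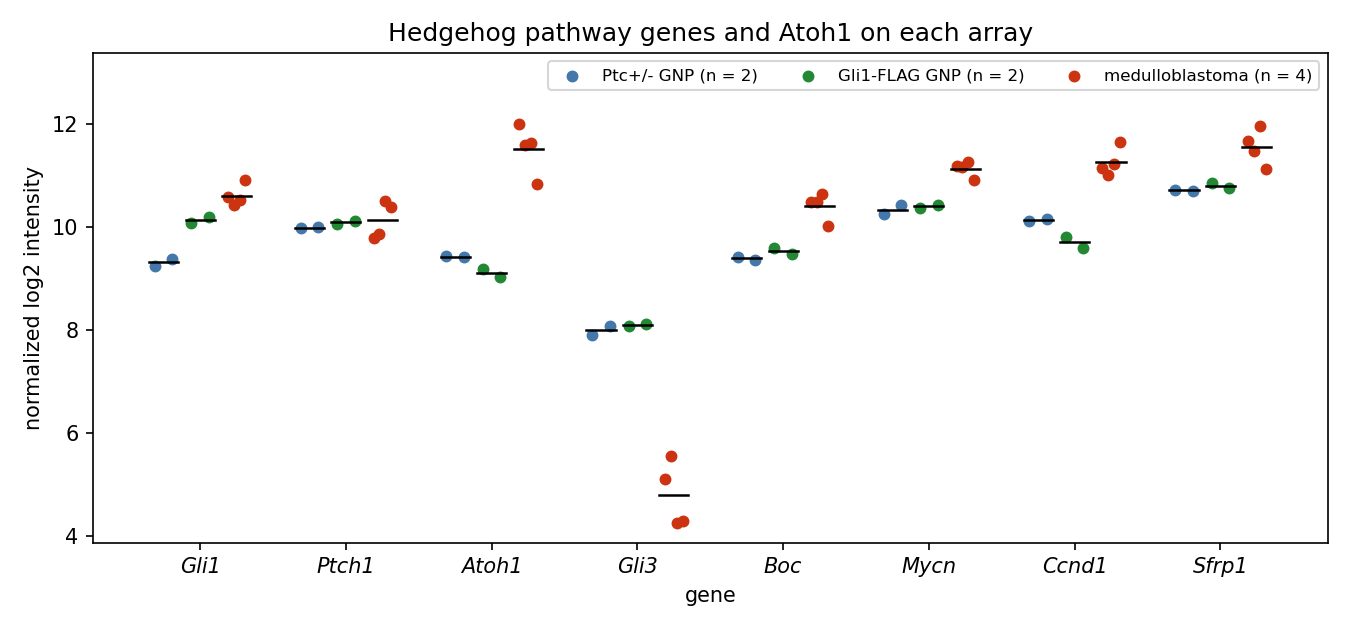
Normalized log2 intensity of hedgehog pathway genes and Atoh1 on each of the 8 arrays (dots) with group means (bars). The tumours sit above both Ptc+/- GNP samples for Gli1 (10.42 to 10.90 against 9.24 and 9.38) and far below them for Gli3 (4.25 to 5.54 against 7.90 and 8.07), while Ptch1 overlaps.

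The largest rise belonged to Sema3e (transcript cluster 6928880), which encodes a secreted guidance semaphorin and was 29.9-fold higher in tumours (log2 fold change 4.90 ± 0.32, SE; adjusted p = 0.000902). Smoc1, which encodes a secreted matricellular protein, rose 12.1-fold. Th, encoding tyrosine hydroxylase, rose 11.8-fold, Lmo1, a LIM-only transcriptional cofactor gene, 9.35-fold, and Tecta, encoding a matrix protein of the inner ear, 9.25-fold. The ephrin receptor gene Epha8, the retinol carrier gene Rbp4, the tendon transcription factor gene Scx and the neuronal pentraxin gene Nptx1 each rose at least 8.01-fold. Bex4 (transcript cluster 7013992) showed the largest fall (log2 fold change -5.26), from 8.68 ± 0.02 to 3.43 ± 0.53 (adjusted p = 0.000800). The transcription factor genes Lhx5 (-3.77) and Msx2 (-3.74), Sypl2 (-3.85), the glypican gene Gpc4 (-3.35), the small GTPase gene Gem (-3.32) and the glutamate receptor gene Grm3 (-3.29) were also among the 10 largest falls, as were Fos, Atf3 and Tfap2b, described with their lists. Bex4, Msx2, Gem and Lhx5 in tumours (means of 3.43, 3.68, 4.21 and 4.46) and Tecta and Sema3e in Ptc+/- GNPs (4.40 and 4.46) lay at or under the highest level of the Y-linked genes on arrays with little of their signal (4.55), so these levels cannot be told from background and the folds and their ranks are not exact. All 4 tumours lay beyond both Ptc+/- GNP samples for each of these genes because the rule that named them required it. Sema3e, Smoc1, Th, Epha8, Scx, Bex4, Sypl2, Lhx5 and Gpc4 kept their calls on leaving out each array in turn. Lmo1 (adjusted p = 0.0967), Tecta (0.0696), Rbp4 (0.128), Nptx1 (0.130), Msx2 (0.156), Gem (0.0521) and Grm3 (0.215) did not pass without Ptc+/- GNP replicate 1. Without replicate 2, Rbp4 (0.0713), Nptx1 (0.0956), Msx2 (0.101) and Grm3 (0.119) did not, and Grm3 also missed it without either Gli1-FLAG array (0.0663 and 0.0666), medulloblastoma 1 (0.0669) or medulloblastoma 4 (0.0570), and with the replicate block (0.0747).

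Of 16 measured cyclins, G1 kinases and their inhibitors, 6 rose, 0 fell and 10 did not pass (7 and 0 adjusted over the list alone). The list rose in camera, with a median of 0.35 (adjusted p = 0.0273; adjusted p = 0.718 with an estimated correlation, fry adjusted p = 0.0129). Its call was lost without medulloblastoma 1 (adjusted p = 0.0698) or with the replicate block (adjusted p = 0.0693). The members that moved include drivers and inhibitors of the cycle. Cdkn2a, which encodes the inhibitor p16 and the p53 activator Arf, rose 9.49-fold (8.46 ± 0.99, SD, n = 4, against 5.21 ± 0.08, SD, n = 2; adjusted p = 0.0158). Cdkn2b, which encodes a related inhibitor, rose by 1.45 ± 0.13 (SE; adjusted p = 0.00181), and Cdk6 and Ccnd1, which drive G1, rose by 1.25 ± 0.14 (adjusted p = 0.00406) and 1.12 ± 0.20. Cdkn2b kept its call without each array. Cdkn2a lost it without Ptc+/- GNP replicate 1 (adjusted p = 0.127) or 2 (0.0838), Ccnd1 likewise (0.122 and 0.0804), and Cdk6 without replicate 1 (0.0518).

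S phase and mitosis genes, of which 28 of 28 and 31 of 31 were high in Ptc+/- GNPs, did not pass as lists. Of 28 measured S phase genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; median -0.15; adjusted p = 0.548). The histone mRNA-binding gene Slbp fell by 1.18, the ribonucleotide reductase gene Rrm1 fell by 0.64, and the chromatin assembly gene Chaf1a rose by 0.89. Of 31 measured mitosis genes 0 rose and 3 fell (0 and 0 adjusted over the list alone; median -0.18; adjusted p = 0.172), namely Ect2 (-0.66), Bub1 (-0.77) and Top2a (-0.69). Of 19 measured p53 targets 4 rose and 3 fell (7 and 7 adjusted over the list alone). Sesn2 rose by 1.24 and Phlda3 by 2.13, while Plk2 fell by 1.73 and Btg2 by 1.62. The p53 list had a median of -0.04, which was 0.09 with arrays centred on their medians, and a mean of 0.03 (adjusted p = 0.949). Only Plk2 among these 10 genes kept its call without each array, and the highest adjusted p was 0.236 for Top2a without Ptc+/- GNP replicate 1. Chaf1a, Rrm1, Ect2, Bub1 and Top2a also lost theirs without either Gli1-FLAG array (0.0620 to 0.0925). Chaf1a, Rrm1, Ect2 and Bub1 lost theirs with the replicate block (0.0618 to 0.0969), and Rrm1 (0.148) and Top2a (0.109) with arrays centred on their medians.

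Immediate early genes, which cells switch on within minutes of a stimulus and during tissue dissociation, were lower in tumours. Of 21 measured, 14 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -1.91. The list fell in camera (adjusted p = 8.05e-09) and in fry (adjusted p = 0.000178), with adjusted p = 0.266 with an estimated correlation. Fos went from 11.17 ± 0.22 (SD, n = 2) to 6.90 ± 0.50 (SD, n = 4), a 19.3-fold difference (adjusted p = 0.00104), and Atf3 from 9.42 ± 0.33 to 5.48 ± 0.28 (adjusted p = 0.000610). The Kruppel-like factor genes Klf6 (-2.93), Klf4 (-3.09) and Klf2 (-2.78) fell as well. The 1 member that rose, named after its values were seen, was Fosl2 (log2 fold change 1.496; adjusted p = 0.0183). Fos, Atf3, Klf2, Klf4 and Klf6, and the call of the list, held without each array in turn. The list was alike in both GNP groups, with means relative to each gene's average of 0.73 and 0.93 in Ptc+/- GNPs, 0.72 and 0.82 in Gli1-FLAG GNPs, and -0.89 to -0.73 in tumours.

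The lists of endothelium and of microglia moved in opposite directions in camera. Of 16 measured endothelial markers 9 fell and 0 rose (10 and 0 adjusted over the list alone), and the list fell with a median of -1.32 (adjusted p = 0.000127; adjusted p = 0.897 with an estimated correlation, fry adjusted p = 0.0609). Kdr, which encodes the main VEGF receptor, fell by 3.02, the angiopoietin receptor gene Tek by 2.60, Pecam1 by 2.00 and Esam by 1.90. The list's call held without each array. Ptc+/- GNP replicate 1 carried more of these transcripts than replicate 2 (list mean 1.24 against 0.04). Without replicate 1 the differences of Kdr, Tek, Pecam1 and Esam were -2.27, -1.70, -1.37 and -1.23, and their calls were lost (adjusted p = 0.0543, 0.0566, 0.0542 and 0.0894), as were most of the 104 named calls. Tek and Esam also lost theirs with the replicate block (0.0608 and 0.0516). Of 19 measured microglia and macrophage markers 5 rose and 0 fell (6 and 1 adjusted over the list alone), and the list rose with a median of 0.86 (adjusted p = 0.0254; adjusted p = 0.959 with an estimated correlation, fry adjusted p = 0.211). With arrays centred on their medians 8 members rose. The lysosomal gene Cd68 and the complement genes C1qb, C1qc and C1qa rose by 2.04, 2.04, 2.00 and 1.64. The microglia list lost its call without Ptc+/- GNP replicate 2 (adjusted p = 0.127) or medulloblastoma 1 (0.0698), and its 4 genes lost theirs without either Ptc+/- GNP array (0.0681 to 0.127), as did C1qa without medulloblastoma 1 (0.0504).

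Markers of the other non-neural cell types did not pass as lists. Of 20 measured markers of pericytes, fibroblasts and meninges 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.179). The collagen gene Col5a2 fell by 2.15, the fibronectin gene Fn1 by 1.58 and the laminin gene Lamb1 by 1.51, and Mgp rose by 1.93. The tumour level of Col5a2 (mean 4.27) lay under 4.55 and cannot be told from background, so its fall is not exact. This list too was higher on Ptc+/- GNP replicate 1 (0.91) than on replicate 2 (-0.73). Of 13 lymphocyte markers 1 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.27; adjusted p = 0.172), the co-receptor gene Cd4 (1.74-fold). With arrays centred on their medians 3 lymphocyte markers rose and their median was 0.70. Of 3 erythrocyte genes 1 fell (2 adjusted over the list alone; median -0.49, adjusted p = 0.491, fry adjusted p = 0.0357), the heme synthesis gene Alas2 (by 1.24). None of 7 choroid plexus and ependyma genes passed, also adjusted over the list alone (median -0.07, and 0.34 with 1 rise with arrays centred on their medians; adjusted p = 0.936). Col5a2 kept its call without each array, and Fn1, Lamb1, Mgp, Cd4 and Alas2 lost theirs without Ptc+/- GNP replicate 1 (adjusted p = 0.0668 to 0.182). Lamb1, Mgp, Cd4 and Alas2 also lost theirs without either Gli1-FLAG array (0.0533 to 0.0638), Lamb1 with the replicate block (0.0925), and Alas2 with arrays centred on their medians (0.0548).

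**Figure D2:**
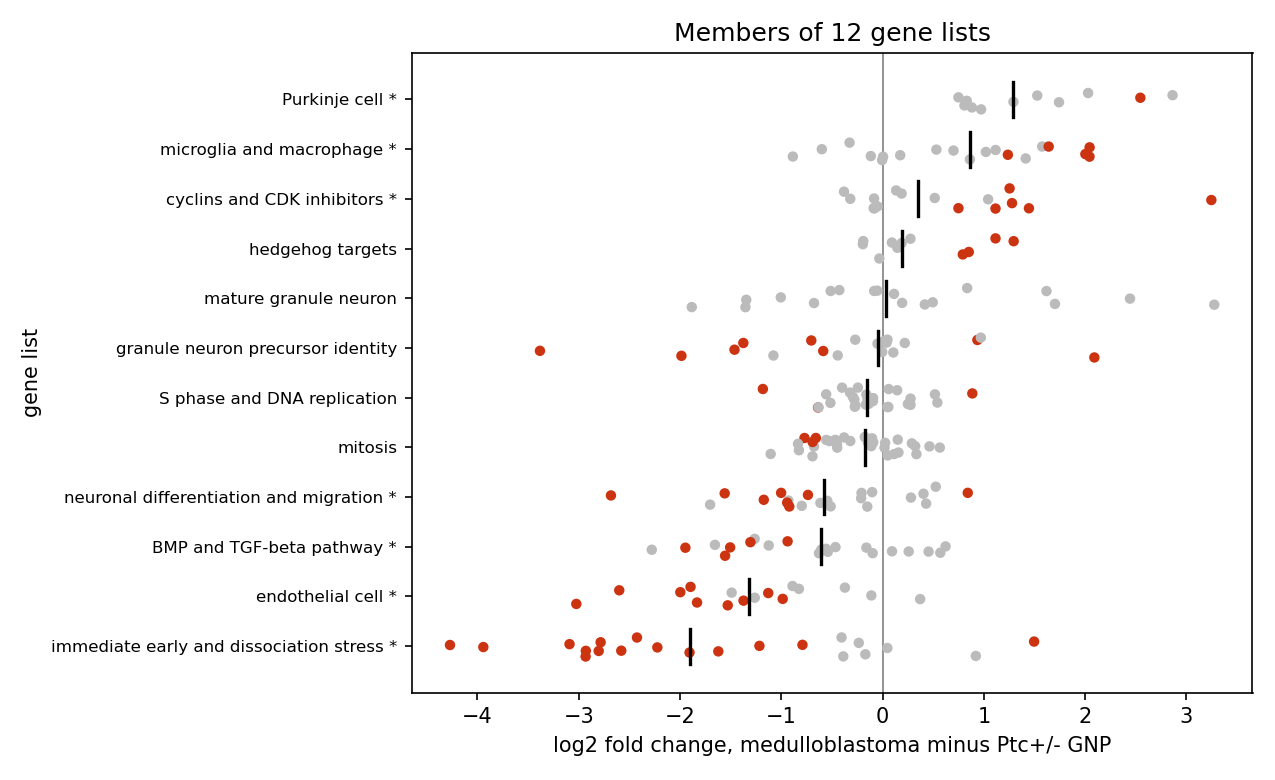
Log2 fold changes, medulloblastoma minus Ptc+/- GNP, of the measured members of 12 gene lists (dots; red passed the adjusted threshold over all rows, grey did not; vertical bars are list medians; asterisks mark lists past camera's threshold). Immediate early genes lie lowest (median -1.91) and Purkinje cell genes highest (median 1.29).

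Of 22 measured genes of neuronal differentiation and migration, 7 fell and 1 rose (9 and 1 adjusted over the list alone), and the list fell in camera with a median of -0.58 (adjusted p = 0.0394; adjusted p = 0.959 with an estimated correlation, fry adjusted p = 0.241). The guidance gene Sema6a fell by 1.56, the growth cone gene Gap43 by 0.92 and the microtubule regulator gene Stmn2 by 0.74, while Cxcr4, which encodes the receptor that holds GNPs in the outer cerebellum, rose by 0.84. The list lost its call without Ptc+/- GNP replicate 2 (adjusted p = 0.0536), medulloblastoma 1 (0.0883) or medulloblastoma 4 (0.146), and the named genes lost theirs without either Ptc+/- GNP array (0.0740 to 0.179), as did Gap43 and Stmn2 without either Gli1-FLAG array (0.0622 to 0.0658) or medulloblastoma 1 (0.0624 and 0.0636). With arrays centred on their medians 3 genes of the list fell and 1 rose, its median was -0.59, and Gap43 and Stmn2 lost their calls (0.0716 and 0.0732).

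Markers of mature cerebellar neurons varied between tumours. All 11 measured Purkinje cell genes had positive differences, and the list rose with a median of 1.29 (adjusted p = 0.0254; adjusted p = 0.959 with an estimated correlation, fry adjusted p = 0.187), but only the calcium-binding protein gene Pvalb passed (5.84-fold; adjusted p = 0.0381), and 0 adjusted over the list alone. The list mean was 2.22 on medulloblastoma 2 and 1.21 on medulloblastoma 1, against -0.20 and -0.37 on medulloblastomas 3 and 4, and -0.77 and -0.76 in Ptc+/- GNPs. It lost its call without medulloblastoma 1 (adjusted p = 0.0698), and Pvalb lost its call without either Ptc+/- GNP array (0.235 and 0.125), either Gli1-FLAG array (both 0.0714), medulloblastoma 1 (0.0783) or medulloblastoma 4 (0.0569). None of 18 mature granule neuron genes passed, also adjusted over the list alone (median 0.03; adjusted p = 0.870), and their mean ran from -1.59 on medulloblastoma 4 to 1.598 on medulloblastoma 2. None of 16 glutamate and GABA receptor genes passed either, also adjusted over the list alone (adjusted p = 0.548), and 1 rose with arrays centred on their medians. Of 10 GABAergic interneuron genes 2 fell (3 adjusted over the list alone; median -0.54; adjusted p = 0.178), Lhx5 and Pax2, the latter by 1.53. Of 6 genes of unipolar brush cells and cerebellar nuclei, Eomes fell by 2.72 and Lhx2 rose by 2.00 (1 and 1 adjusted over the list alone; median 0.13; adjusted p = 0.870).

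The glial lists did not pass. Of 15 oligodendrocyte lineage genes 3 rose and 1 fell (3 and 1 adjusted over the list alone). Those that rose were Olig1 (5.24-fold), Olig2 (3.02-fold) and Pdgfra (2.24-fold), which mark early progenitors, and the one that fell was Ugt8a (by 1.78), which makes a myelin lipid. Camera's direction was up (adjusted p = 0.548), although the median was -0.31 and the mean -0.10. Of 18 astrocyte and Bergmann glia genes 2 rose and 0 fell (1 and 0 adjusted over the list alone), the GABA transporter gene Slc6a11 (by 1.92) and Apoe (by 1.00). The median was 0.33 and the mean -0.14, with camera's direction up (adjusted p = 0.8004). The list means ran from -1.74 on medulloblastoma 3 to 1.10 on medulloblastoma 2 for astrocytes, and from -1.12 to 0.93 on the same arrays for oligodendrocytes. Pax2, Olig1, Olig2, Pdgfra, Ugt8a, Slc6a11 and Apoe lost their calls without either Ptc+/- GNP array (adjusted p up to 0.259, for Ugt8a), and Lhx2 without replicate 1 (0.0827), while Eomes kept its call without each array. Apoe and Ugt8a also lost theirs without either Gli1-FLAG array (0.0817 to 0.0880), and Slc6a11 and Ugt8a with the replicate block (0.0618 and 0.153).

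**Figure D3:**
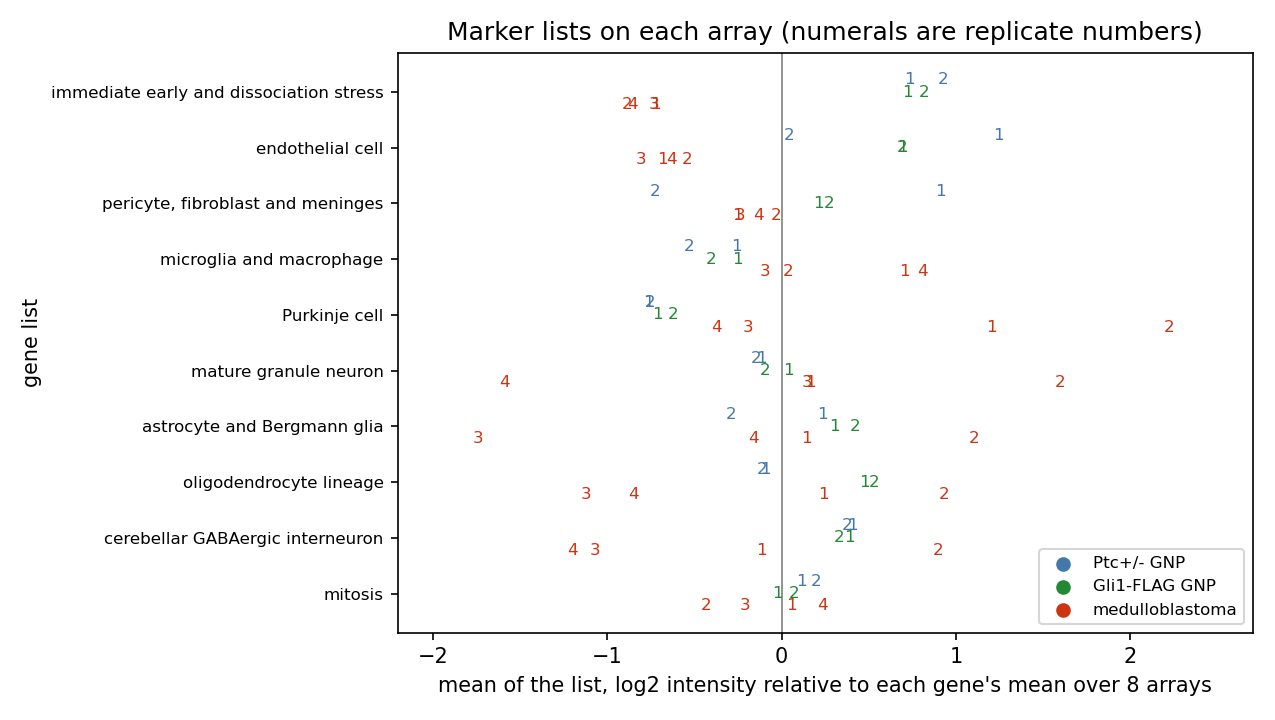
Mean of 10 marker lists on each array, in log2 units relative to each gene's mean over the 8 arrays (numerals are replicate numbers, colours are groups). Medulloblastoma 2 is highest for Purkinje (2.22) and mature granule neuron genes (1.598), and Ptc+/- GNP replicate 1 is highest for endothelial genes (1.24).

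Among the signalling lists, that of the BMP and TGF-beta pathway fell. Of 21 measured genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.0254; adjusted p = 0.367 with an estimated correlation, fry adjusted p = 0.000946). Those that moved act in different ways: Bmpr1b and Tgfbr1, which encode receptors, fell 2.84-fold and 2.94-fold, the inhibitory Smad gene Smad7 fell by 1.95, and Fst, which encodes an extracellular antagonist, fell by 0.94. The list lost its call without medulloblastoma 1 (adjusted p = 0.0654). Of 18 Notch pathway genes 1 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.19; adjusted p = 0.548). Lfng, which encodes a modifier of Notch receptors, rose by 1.57, while the ligand gene Dll1 (-2.21), the target gene Hey2 (-2.14) and the pathway's transcription factor gene Rbpj (-0.84) fell. The tumour level of Dll1 (mean 4.19) cannot be told from background. Of 18 Wnt pathway genes 2 rose and 5 fell (3 and 5 adjusted over the list alone; adjusted p = 0.548), and 0 rose and 4 fell with arrays centred on their medians. Those that fell included Dkk3 (-1.22), Rnf43 (-1.23), Tcf7l2 (-1.48) and Sfrp4 (-1.285). Of 12 IGF pathway genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.936). The receptor substrate gene Irs1 rose by 0.87 and Igfbp3 by 1.35, Igfbp4 fell by 1.07, and Igf2r fell too (log2 fold change -1.215). The median of this list lay near 0 and changed sign with arrays centred on their medians. Of 13 neural stem cell genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; median -0.38; adjusted p = 0.548). Pax3 fell by 3.26 and kept its call without each array, Msi2 fell by 0.62, and Hmga2 rose by 1.00. Apart from Pax3 and Sfrp4, every gene named here lost its call without Ptc+/- GNP replicate 1. On leaving out each of the 8 arrays in turn, Sfrp4 lost its call in 4 settings and Igf2r in 5. Igfbp4, Msi2 and Hmga2 also lost theirs without either Gli1-FLAG array (0.0505 to 0.0769). With the replicate block Fst (0.0539), Msi2 (0.0838) and Hmga2 (0.0558) lost theirs, as did Fst with arrays centred on their medians (0.140).

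The remaining lists did not pass. Of 15 matrix remodelling genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; median -0.67; adjusted p = 0.207), with the matrix genes Tnc (-2.91) and Nid1 (-1.86) falling and Mmp2 and Timp2 rising by 1.46 and 1.78. Of 10 imprinted genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; median -0.34; adjusted p = 0.178, fry adjusted p = 0.0300). The zinc finger gene Plagl1 fell by 2.32 and the growth restraint gene Grb10 by 2.25, while Nnat rose by 0.58. Of 17 hypoxia and glycolysis genes the hexokinase gene Hk2 rose (2.36 ± 0.48, SE) and 0 fell (1 and 0 adjusted over the list alone; median 0.34; adjusted p = 0.420). Of 14 ribosomal protein genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.36; adjusted p = 0.152), namely Rpl19 (0.60), whose dimmer row differed by 0.12 (adjusted p = 0.881). Of 15 respiratory chain genes Ndufs1 fell by 0.70 (0 rises and 1 fall adjusted over the list alone; median 0.10; adjusted p = 0.548). None of 14 interferon response genes (median 0.22; adjusted p = 0.420) or 7 antigen presentation genes (median 0.35; adjusted p = 0.890) passed, also adjusted over the list alone. With arrays centred on their medians these medians were 0.645 and 0.741, and 1 antigen presentation gene rose. Plagl1 kept its call without each array, whereas Tnc, Nid1, Mmp2, Timp2, Grb10, Nnat, Hk2, Rpl19 and Ndufs1 lost theirs without Ptc+/- GNP replicate 1 (adjusted p = 0.0591 to 0.184). Nnat, Rpl19 and Ndufs1 also lost theirs without either Gli1-FLAG array (0.0520 to 0.0753), and with the replicate block (0.0594, 0.0775 and 0.0660), and Rpl19 with arrays centred on their medians (0.0553).

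Scaling changed the counts or medians of further lists against Ptc+/- GNPs. With arrays centred on their medians, neural stem cell genes had a median of -0.09 with 2 rises and 2 falls, unipolar brush cell and nuclear genes a median of 0.53, GABAergic interneuron genes -0.28, and erythrocyte genes -0.08 with 0 falls. Oligodendrocyte genes had a median of -0.09 with 4 rises and 1 fall, pericyte, fibroblast and meninges genes a median of -0.36, imprinted genes -0.18, ribosomal protein genes 0.55 with 0 rises, and glutamate and GABA receptor genes 0.66. GNP identity genes had 2 rises and 4 falls (median -0.15), hypoxia and glycolysis genes 2 rises (median 0.43), S phase genes 1 rise and 1 fall, respiratory chain genes 2 falls (median 0.29), and astrocyte and Bergmann glia genes 2 rises and 1 fall.

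The comparison of the GNP groups asks what Gli1-FLAG expression and Ptch1 heterozygosity change relative to each other in precursors of the same age. Gli1 was 1.78-fold higher in Gli1-FLAG GNPs (10.14 ± 0.08, SD, n = 2, against 9.31 ± 0.10, SD, n = 2; log2 difference 0.83 ± 0.20, SE; adjusted p = 1 in limma), a difference that passed when adjusted over the list alone (1 of 11 hedgehog targets) but not over all rows. The other targets did not pass: Ptch1 differed by 0.10 ± 0.27, Ccnd1 by -0.44 ± 0.23, Hhip by -0.73 ± 0.65 and Mycn by 0.06 ± 0.18. In limma's fit 0 of 16317 rows passed, with 525 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0717. The fit shares its spread with the tumours, which vary more (median SD 0.299, against 0.0899 in Gli1-FLAG and 0.140 in Ptc+/- GNPs). Even the Y-linked Eif2s3y (-4.67, SE 1.34) and Kdm5d (-3.73, SE 1.03) did not pass in it, their signal being low on medulloblastoma 3. So 0 calls do not show that the GNP groups, which also differ in Y-linked signal, are alike. The groups did not overlap in 46.3% of rows, where chance gives 33.3%. Rows share arrays, so 1 array of unlike composition can part many rows together, and the excess does not establish a difference of genotype. Array weights gave 3 calls, leaving out medulloblastoma 3 gave 4, a fit on the 4 GNP arrays gave 2, and eBayes with trend and robust settings, quantile normalization of log2 values and the replicate block gave 1 each. The 4 without medulloblastoma 3, named after their values were seen, were Olfr1338 (-1.98), the Y-linked Kdm5d (-3.76) and Eif2s3y (-4.70), and 1 row unnamed here (-5.28). Those with the lowest p, all short of the threshold, included the odorant receptor genes Olfr1295, Olfr893 and Olfr911-ps1 with Pdcl2 and Prss35 on the higher side, and Olfr1510, Prmt8, Lrrc15, Vit and Adgrv1 on the lower side. Prmt8, which encodes an arginine methyltransferase of neurons, was at 5.27 ± 0.19 in Gli1-FLAG and 7.54 ± 0.12 in Ptc+/- GNPs. Both group means of Olfr1295, Olfr893, Olfr911-ps1, Pdcl2, Olfr1510, Lrrc15 and Olfr1338 lay under 4.55, so they cannot be told from background.

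With all arrays and no block, 0 gene lists passed between the GNP groups by camera at the preset correlation, with an estimated correlation or by fry, while 2 passed with the replicate number as a block. Members past the threshold were 0 in every list over all rows and, apart from Gli1, adjusted over the list alone. The oligodendrocyte lineage came closest, with 14 of 15 genes higher in Gli1-FLAG GNPs (median 0.68; adjusted p = 0.0582; adjusted p = 0.971 with an estimated correlation). The oligodendrocyte lineage list passed with the replicate block (adjusted p = 2.0e-06) and without medulloblastoma 2 (adjusted p = 0.00951), medulloblastoma 3 (0.00963), medulloblastoma 4 (0.0230) or Ptc+/- GNP replicate 1 (0.0214). Genes of the astrocyte and Bergmann glia list were higher in 17 of 18 cases (median 0.43; adjusted p = 0.174) and passed with the replicate block (adjusted p = 0.00632) and without medulloblastoma 3 (0.00963) or Ptc+/- GNP replicate 1 (0.0214). Genes of the endothelial cell list were higher in Gli1-FLAG GNPs without Ptc+/- GNP replicate 1 (adjusted p = 4.03e-13) and lower without replicate 2 (adjusted p = 4.69e-06). The list named pericyte, fibroblast and meninges turned in the same way (adjusted p = 4.91e-20 and 4.14e-10), as did that of extracellular matrix remodelling (0.0383 and 0.0456). In total 8 lists passed without replicate 1 and 4 without replicate 2. The median, mean and camera's direction were not all of 1 sign for the lists of Notch, BMP and TGF-beta, lymphocytes, unipolar brush cells, interferon response, imprinted genes and glutamate and GABA receptors.

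Tumours were also set against Gli1-FLAG GNPs, the precursors that share the tagged Gli1. Y-linked signal differs here too: Eif2s3y was at 4.54 and 4.12 on the Gli1-FLAG arrays and at 8.97, 8.32, 4.55 and 8.84 on the tumours. This comparison therefore does not separate it from the disease. Gli1 was 1.38-fold higher in tumours and did not pass (0.47 ± 0.17, SE; adjusted p = 0.127). Ccnd1 rose 2.95-fold (log2 fold change 1.56 ± 0.20, SE; adjusted p = 0.00763) and Mycn 1.66-fold (adjusted p = 0.0313), whereas Sfrp1 (0.76 ± 0.23; adjusted p = 0.0794) and Ptch1 (0.04 ± 0.24; -0.03 with arrays centred on their medians) did not pass. Of 11 hedgehog targets 2 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0629, fry adjusted p = 0.0215), and the list passed without medulloblastoma 2 (adjusted p = 0.0466). Among pathway components Smo, which encodes the hedgehog signal transducer, rose by 1.15, and Gli3 (-3.31), Stk36 (-0.94) and Ift88 (-0.84) fell. Atoh1 rose by 2.41. In limma's fit 1677 rows (10.3%) passed, 758 rising and 919 falling, and 882 changed at least 2-fold. All tumours lay beyond both Gli1-FLAG samples in 41% of rows, where chance gives 13.3%, an excess that was likewise not tested. The count was 62 and 71 without Gli1-FLAG GNP replicates 1 and 2, 838 and 821 without Ptc+/- GNP replicates 1 and 2, and 802 without medulloblastoma 1. Ccnd1 lost its call without Gli1-FLAG GNP replicate 1 (adjusted p = 0.0912) or 2 (0.108). Mycn lost its call without replicates 1 (0.2498) or 2 (0.199), either Ptc+/- GNP array (0.0541 and 0.0562), medulloblastoma 1 (0.0681) or medulloblastoma 2 (0.0519), and with the replicate block (0.0599) or arrays centred on their medians (0.0950).

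Prmt8 showed the largest rise against Gli1-FLAG GNPs, 33.0-fold (10.32 ± 0.57, SD, n = 4, against 5.27 ± 0.19, SD, n = 2; adjusted p = 0.000863). It was followed by Sema3e (27.0-fold), Cdkn2a (12.8-fold), the lysosomal glycoprotein gene Gpnmb (12.01-fold) and Lmo1 (11.4-fold). The largest falls were those of Bex4 (-5.52), Fos (-4.30), Sypl2 (-3.94), Msx2 (-3.92) and Gem (-3.55). The tumour levels of Bex4, Msx2 and Gem cannot be told from background, so these folds are not exact. Prmt8, Sema3e, Bex4, Fos and Sypl2 kept their calls on leaving out each array. Cdkn2a, Gpnmb, Lmo1, Msx2 and Gem lost theirs without Gli1-FLAG GNP replicate 1 (adjusted p = 0.0739 to 0.203) or replicate 2 (0.0617 to 0.176). Gpnmb also lost its call without medulloblastoma 1 (0.0524), and Msx2 without either Ptc+/- GNP array (0.0521 and 0.0531).

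Of the 34 lists 7 passed against Gli1-FLAG GNPs by camera, and 0 did so with an estimated correlation. By fry 5 passed, of which 3 were among the 7 and the others were hedgehog targets (adjusted p = 0.0215) and imprinted genes (adjusted p = 0.0165), which camera did not call. Because the tumours are the same samples as before, these results are not independent of those against Ptc+/- GNPs. The immediate early list fell (14 fell and 1 rose of 21, and 14 and 1 adjusted over the list alone; median -2.10; adjusted p = 6.51e-09; adjusted p = 0.260 with an estimated correlation, fry adjusted p = 0.000294). The endothelial list fell (8 of 16 members fell, and 10 adjusted over the list alone; median -1.16; adjusted p = 4.5e-06; adjusted p = 0.734 with an estimated correlation, fry adjusted p = 0.0578). The BMP and TGF-beta list fell (4 members of 21, and 5 adjusted over the list alone; median -0.68; adjusted p = 0.00894; adjusted p = 0.267 with an estimated correlation, fry adjusted p = 0.00227). The list of cyclins and their inhibitors rose (5 members of 16, and 6 adjusted over the list alone; adjusted p = 0.00894; adjusted p = 0.606 with an estimated correlation, fry adjusted p = 0.00922). Purkinje cell genes rose as a list, with 11 of 11 positive and 0 past the threshold by either adjustment (median 1.43; adjusted p = 0.0226; adjusted p = 0.983 with an estimated correlation, fry adjusted p = 0.335). The microglial list rose (4 members rose and 1 fell of 19, and 5 and 1 adjusted over the list alone; median 0.55; adjusted p = 0.0243; adjusted p = 0.983 with an estimated correlation, fry adjusted p = 0.335). The list of neuronal differentiation and migration fell (3 members fell, 1 rose and 18 did not pass of 22, and 8 and 1 adjusted over the list alone; adjusted p = 0.0271; adjusted p = 0.983 with an estimated correlation, fry adjusted p = 0.335). The Purkinje list lost its call without medulloblastoma 1 (adjusted p = 0.0636), the microglial list without Gli1-FLAG GNP replicate 2 (0.0732) or medulloblastoma 1 (0.0777), and the neuronal differentiation list without Gli1-FLAG GNP replicate 1 (0.0574), medulloblastoma 1 (0.0777) or medulloblastoma 4 (0.133). The median, mean and camera's direction were not all of 1 sign for the lists of hedgehog pathway components, mature granule neurons, S phase, the IGF pathway, choroid plexus and the respiratory chain.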

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

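Apart from planned settings, the tests in this part were chosen after the results they bear on were seen. The planned settings were fry, the estimated correlation, the fit against all 4 GNP arrays and the centring of arrays on their medians. The tests by a slope on endothelial genes and by S phase and mitosis genes took the place of earlier tests, whose values are given as well. The values of the S phase and mitosis genes per array were known when they were chosen as a test. Standard errors in this part are over genes, which share the arrays, and do not measure the spread between samples. The 2 tests on medulloblastoma 2 were first read against their spread over genes and are now read against a widened spread between tumours.

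With the tumours set against all 4 GNP arrays, 4218 rows passed the threshold. Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, gave as many. The highest count of the other splits was 1. The real split is thus the most extreme of them, but no share under 0.0286 can be reached with 35 splits. It was also known to part the arrays before this test, so the test does not exclude chance. The age of the animals, the preparation of the samples and the joint presence of both alterations follow the same split and were not separated from the disease.

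The fall of the immediate early genes, led by Fos, Atf3, Klf4 and Klf6, has 14 of its 21 measured members among the transcripts high in Ptc+/- GNPs and shares 1 with another list. Blood vessel cells carried along with the GNPs would need the list to follow the endothelial genes. Over the 4 GNP arrays its mean slope on them was -0.165 (SE 0.047 over genes). In the earlier test the vessel-rich Ptc+/- GNP 1 had the lower list mean of the Ptc+/- pair (0.73 against 0.93). Both values rest largely on that pair, since the Gli1-FLAG arrays had nearly equal endothelial means (0.695 and 0.689). The list thus did not rise with the endothelial genes on these arrays, which are too few to exclude vessel cells. Scaling of the arrays does not account for the fall, since the median of the list was -1.97 with each array centred on its median. Isolation of the GNPs as cells, which may switch on Fos and its relatives, stays open, as does a difference between tumour and precursor or in age: the GNP groups differed by -0.062 (SE 0.065), which each of these allows. They cannot be told apart because every GNP sample was purified and no tumour is labelled so.

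Of the endothelial markers 9 of 16, such as Kdr, fell, while 5 of 19 microglial markers, such as Cd68 and C1qb, rose. The lists' calls were lost with an estimated correlation (adjusted p = 0.897 and 0.959) and by fry (adjusted p = 0.0609 and 0.211). Of these lists 6 of 16 and 7 of 19 members are high in Ptc+/- GNPs, and 1 and 0 are shared with other lists. Fewer non-neuronal cells of every kind in the tumours would lower both. The microglial mean exceeded the endothelial mean by 2.07 (SE 0.304 over genes) and was itself higher in tumours by 0.76 (SE 0.21 over genes). Per array the microglial mean was -0.094 to 0.809 in tumours, against -0.261 and -0.531 in Ptc+/- GNPs. The lists thus did not fall together on these arrays, while the rise of the microglial list itself is uncertain by the tests above. The vessel-rich Ptc+/- GNP 1, which exceeded replicate 2 by 1.203 (SE 0.08) for endothelial and 1.64 (SE 0.21) for meningeal genes, is not the whole cause, since the endothelial mean of the tumours also differed by -1.36 (SE 0.189) from Gli1-FLAG GNPs and by -0.71 (SE 0.19) from Ptc+/- GNP 2 alone. A change in vessels or microglia with the tumour, with age, or with the purification of the GNPs stays open and was not tested.

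Medulloblastoma 2 had the highest levels of Pcp2 (10.33, against 8.96, 5.76 and 6.34 in the other tumours), Gabra6 (9.79 against 8.11, 6.77 and 4.41) and Mbp (10.94 against 9.79, 5.97 and 6.10). In the earlier test, 5 of 5 lists of adult cerebellar cell types were highest on it among the tumours. Normal cerebellar tissue in the sample stays open, as does differentiation of tumour cells into granule neurons as a part of the pattern. Differentiation into granule neurons alone would not raise the lists of GABAergic interneurons, astrocytes and oligodendrocytes. These lay 1.01, 0.96 and 0.69 above medulloblastoma 1, values that rest on 1 tumour. S phase and mitosis genes (59 genes), which normal tissue would lower, lay -0.457 from the mean of the other tumours. That is less than 2 times 0.239, the spread between those tumours widened for comparing 1 tumour with a mean. Without the widening it would be more than 2 times the spread, so the test does not decide. The Purkinje list, which differentiation into granule neurons alone would not raise, was 1.02 above the next tumour. The spread between the others, widened in the same way, was 0.998. That widening suits a comparison with the mean of the others and not with the next tumour, so this test does not decide either. The list means were 2.22 on medulloblastoma 2 and 1.21, -0.20 and -0.37 on medulloblastomas 1, 3 and 4. Of the list's 11 members 2 are high in Ptc+/- GNPs and 1 is shared with another list. A single tumour is too little to tell them apart, and no biological explanation from the design was tested.

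Single tumours stood apart in 13 of 156 values tested (122 genes and 34 lists), where chance gives 7.8. The measure is the gap of the highest or lowest tumour to the nearest other, divided by the range of the 4 tumours, and the genes share arrays and are not independent. Medulloblastoma 4 was the highest for Hmga2 (7.97 against 7.09 to 7.22, ratio 0.845), Kdr (6.91 against 6.03 to 6.12, ratio 0.891), Fst (5.08 against 4.77 to 4.81, ratio 0.852) and Col5a2 (4.35 against 4.23 to 4.25, ratio 0.841), whose levels cannot be told from background. It was also the highest for the Notch pathway list (mean 0.46 against -0.37 to -0.23, ratio 0.83) and for Olfr1510 (0.46 against 0, ratio 1), which is at the bottom of the scale. Medulloblastoma 3 was the highest for Sema6a (10.59 against 9.56 to 9.72, ratio 0.847) and Mgp (9.35 against 7.69 to 7.88, ratio 0.888). It was the lowest for Phlda3 (6.96 against 8.30 to 8.39, ratio 0.939), Nnat (11.5 against 11.72 to 11.76, ratio 0.854) and Prss35 (4.82 against 5.01 to 5.02, ratio 0.972). Medulloblastoma 2 was the lowest for Atf3 (5.06 against 5.58 to 5.64, ratio 0.904), and medulloblastoma 1 was the highest for Klf2 (7.18 against 6.82 to 6.84, ratio 0.924).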

How the results depend on the processing

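The setting without Ptc+/- GNP 1 and medulloblastoma 2 was chosen after seeing the data, and the others before. Of 2847 values of named genes under alternatives, 2404 kept their direction and side of the threshold, 416 kept only the direction, 8 newly passed and 19 changed sign. Where a cause is not given, the cause was not tested. Changed rows for tumours against Ptc+/- GNPs, 2687 as reported, numbered 1239 with only those arrays, 1252 with a 2-fold minimum, 4218 against all 4 GNP arrays, 40 without Ptc+/- GNP 1 and medulloblastoma 2, and 128 to 2898 on leaving out 1 array. For the GNP groups, 0 as reported, they numbered 2 with only those arrays, 3 with array weights, 1 each with the replicate block, quantile normalization of log2 values, or trend and robust settings, and 0 to 4 on leaving out 1 array. For tumours against Gli1-FLAG GNPs, 1677 as reported, they numbered 832 with only those arrays, 1066 with the block, 3566 with array weights, 882 with a 2-fold minimum, 540 without Ptc+/- GNP 1 and medulloblastoma 2, and 62 to 1980 on leaving out 1 array. A stricter threshold lowers a count by construction, and a lone array is assumed to vary like the other groups. Fewer arrays weaken a test, but the count against Ptc+/- GNPs rose to 2854 without medulloblastoma 3 and 2898 without medulloblastoma 4.

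Gene lists past the threshold, 7, 0 and 7 as reported in the order above, were 0, 0 and 0 with an estimated correlation, 6, 0 and 5 by fry (where 4 of the 7 calls were lost in each tumour comparison and lists that camera did not call passed), 9, 2 and 7 with the block, 10, 9 and 9 without Ptc+/- GNP 1 and medulloblastoma 2, and 2 to 10, 0 to 8 and 4 to 9 on leaving out 1 array. The replicate numbers do not pair the samples (correlations of residuals between samples of a number from -0.073 to 0.009). Only tumours carry the numbers 3 and 4, so with the block medulloblastomas 3 and 4 are fitted exactly and drop out of every comparison. A result that changes with the block can therefore come from the loss of these tumours. The signs that changed belong to differences short of the threshold. Against Ptc+/- GNPs, Ptch1 was -0.17 and Hhip -0.61 with the block, Nkx2-2 0.29 with arrays centred on their medians, and Igf2 1.38 and Bcl2 0.044 without Ptc+/- GNP 1 and medulloblastoma 2. On leaving out 1 array, Hhip ran from -0.38 to 0.40, Igf2 from -1.691 to 1.295, Bcl2 from -0.38 to 0.002 and Nkx2-2 from -0.28 to 0.17. Between the GNP groups, Mycn was -0.029 without Ptc+/- GNP 1 and medulloblastoma 2 and -0.028 to 0.15 on leaving out 1 array, and Igf2 ran from -0.95 to 2.04. Against Gli1-FLAG GNPs, Ptch1 was -0.27 with the block, -0.034 with arrays centred on their medians, and -0.08 to 0.16 on leaving out 1 array. Rows high in all groups numbered 6696, and 5910 over rows with a symbol or 4952 above the 60th percentile. With the block, the cyclin list against Ptc+/- GNPs lost its call (adjusted p = 0.0693). Camera was not run with arrays centred on their medians, and no values were tested as deposited. Without detection p-values, the limit that background sets on dim rows is unknown.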

Other observations

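Beyond the group comparisons, the tumours differed among themselves in stress and immune genes, which were picked out after their values were seen and not tested. Medulloblastoma 3 had the highest mean of the hypoxia and glycolysis list (1.17 relative to each gene's average, against -0.36 to 0.01 in the other tumours). On it Vegfa, which encodes the main vessel growth factor, was at 10.64 against 8.24 to 9.05, the oxygen sensor gene Egln3 at 9.17 against 6.52 to 6.82, the metabolic kinase gene Pdk1 at 8.38 against 4.58 to 5.92, and Bnip3 at 9.87 against 7.22 to 8.15. Some other members were not highest on it, among them Car9 (5.70, against 5.81 on medulloblastoma 4), Slc2a1 (9.28, against 9.68 on medulloblastoma 2) and Ndrg1 (7.82, against 8.20 on medulloblastoma 2). The same tumour had the lowest mean for astrocyte and Bergmann glia genes (-1.74), and its level of the homeobox gene Otx2 was 4.13, against 7.68, 7.05 and 9.12 in the other tumours and 8.45 to 8.89 in the GNPs. That level of Otx2 lies under 4.55 and cannot be told from background.

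Medulloblastoma 4 had the highest means of the interferon response (1.04, against -0.49 to 0.25 in the other tumours) and antigen presentation lists (1.26, against -0.66 to 0.03). Cd74, which encodes the invariant chain of MHC class II, was at 7.89 on it against 4.63 to 5.58 in the other tumours, and H2-Aa, a class II gene, at 7.22 against 5.54 to 6.36. Glutamate and GABA receptor genes were highest on medulloblastoma 2 (1.26) and lowest on medulloblastoma 4 (-0.78). Among the GNPs, Igf2 was at 10.06 on Ptc+/- GNP 1, 7.06 on Ptc+/- GNP 2, and 9.11 and 9.12 on the Gli1-FLAG arrays.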
